A study of Homo sapiens with 6 samples.

How the data were processed

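The series holds 6 Illumina expression arrays of total RNA from SCC25 cells, 3 untreated controls and 3 grown with 2.0 mM aspirin, all at 72 h, per the labels. Replicate numbers 1 to 3 and the chip of each array (replicates 1 and 3 on chip 1, replicate 2 on chip 2) come from the sample titles. The deposited table gives, per the file headers, a signal intensity for each gene and array, not normalized between arrays and with the background still in it, made with GenomeStudio 1.9.0 per the submitters' processing notes. Genome build and probe annotation are not given in the sources used here. The detection columns are deposited as detection p-values per the file headers, but their values run the other way: they average 0.994 over the 1000 brightest genes and 0.170 over the 1000 dimmest. They were therefore read as a deposited detection score of 1 minus the p-value. The table has 1 line for each of 34694 gene symbols, so its values are summaries over the probes of a gene, while the design had assumed separate probes. 1 gene with a signal of 0 was left out.

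The deposited matrix of intensity values equals this signal minus 1 constant per array (104.9, 115.7, 100.6, 95.4, 110.5, 99.7 for controls 1 to 3 and aspirin 1 to 3), with medians of 7.6, 11.4, 7.8, 6.4, 10.6, 7.5. In it, 15338 of 34687 genes carry their own value, 7171 from LOC100133005 on carry that of the next gene and 12173 from LOC728250 on that of the gene after it, within 0.3 intensity units; 2 are empty and 3 have another value. Ribosomal protein genes average the 99.3 percentile of signal under the names of the signal table and the 88.8 under those of the matrix. The signal table was therefore used, and the matrix, after realigning its names, only as an alternative.

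Signals were background corrected by the normal-exponential model, with the background mean and SD of each array inferred from the detection scores, an offset of 16 was added, and arrays were quantile normalized and log2 transformed with limma 3.58.1 in R 4.3.3. The background was estimated from the 27647 genes (79.7%) whose scores are whole steps of 1 in 770 on all arrays, because the scores of the other genes combine several probes. That restriction was chosen after the data were seen, and the estimate from all listed genes was run as an alternative. The alternative put the background mean at 132 to 175 intensity units, above the median signal of every array (101.9 to 127.0). The estimate used equals, when rounded, the constants subtracted in the deposited matrix. Genes with a score above 0.95 on at least 3 of the 6 arrays were tested, 15128 in all (43.6%). 708 genes with a signal above the background mean plus 3 SD on at least 3 arrays were not tested because their combined score is low, CDKN1A among them, and 2744 were tested without such a signal. 42.3 to 43.7% of genes were detected per array.

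Aspirin was compared with control by limma's linear model and moderated test (lmFit and eBayes) without covariates, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. 32 gene lists for pathways, cell states and other cell types were tested by camera with its preset correlation, 31 of them with at least 5 genes measured, adjusted over the lists, beside camera with an estimated correlation and fry. Members of a list were also adjusted over the list alone. A gene counted as above background on an array where its score exceeded 0.95 or its signal exceeded the background mean plus 3 SD, a definition chosen after the data were seen. For a gene above background on all arrays of 1 group and on no array of the other, the fold is given only as a lower bound. It sets the mean normalized signal of the measured group against that of the other, where each array counts with the gene's own signal or, if higher, the lowest signal of any gene on the detection steps with a score above 0.95 on that array. Such a gene is described as not above background.

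Named are the 15 genes with the largest rise and the 15 with the largest fall among genes past the threshold whose groups do not overlap, leaving out provisional names such as LOC or FLJ; PTGS1, PTGS2, CDKN1A, CCND1, MYC, GDF15, BIRC5 and CXCL8 (listed as IL8); and up to 4 members of each list, from those with the smallest p-values. Genes named outside this rule are marked in the text. Groups, comparisons, lists, this rule and the other settings to be tried were fixed before the data were examined. Gene names are those of the table; a RefSeq table for GRCh38 was used only for current names, and of the genes tested 9720 matched a current symbol, 1776 a synonym and 3632 neither.

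Arrays of the same replicate number deviated from their group means together, with correlations of 0.508, 0.516 and 0.320 between control and aspirin for replicates 1 to 3, so the numbers were taken as pairs, a pairing that comes from the data and not from the labels. A fit with the replicate number as a block was run beside the unpaired fit. The other settings were no background correction, a normal-exponential fit with an offset of 50 and no detection scores, median scaling, cyclic loess, the matrix values, stricter detection filters and none, the chip as a block, chip 1 arrays only, eBayes with trend and robust options, array weights, an adjusted p under 0.01, an ordinary test of both groups, log2 signals without normalization for the similarity of arrays, and leaving out each array and each replicate number. The estimate of the background from all listed genes and a filter on the signal itself were added after the data were seen.

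The steps were tested on simulated data made from these 15128 genes for the comparison of aspirin with control, with 50 genes changed at each size. Changes of 0.5, 1, 2 and 3 log2 units were called for 8, 43, 50 and 50 of the 50, and 16 of 14928 unchanged genes were called (0.107%). A list shifted by -1 was called, as was 1 of the 30 other lists. The simulated noise was independent between genes and arrays, without replicate effects, and far fewer genes changed than the 3059 called in the data. The call rates may therefore differ in the data, and the list test could not show false calls from correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.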

Results

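SCC25 is an established cell line from an oral squamous cell carcinoma. Gene expression was measured with Illumina expression arrays in total RNA of SCC25 cells grown for 72 h with 2.0 mM aspirin, an inhibitor of the prostaglandin-forming cyclooxygenases, or without it. The series asks how aspirin alters the expressed genes of this oral cancer line. Each group had 3 arrays, numbered 1 to 3, and replicates 1 and 3 of both groups were on one chip while replicate 2 of both was on another. The median signal of an array was between 101.9 and 127.0 intensity units over a mean background of 95.4 to 116, and 14691 to 15170 of the 34694 listed genes were detected per array. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

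Arrays of the same group correlated at r = 0.977 to 0.991 across genes and arrays of different groups at r = 0.947 to 0.966. The first principal component, with 60.4% of the variance, separated the treated from the untreated arrays, and the second, with 22.5%, set both replicate 1 arrays apart. 420 genes differed between replicate numbers over both groups at an adjusted p under 0.05. Among them, TIMP1, an inhibitor of matrix metalloproteinases, was lower on the replicate 1 arrays than on those of replicates 2 and 3 by 2.75 and 2.81 on the log2 scale, and the noncoding RNA MEG3 by 2.34 and 2.17; this pair was chosen after its values were seen.

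**Figure D1:**
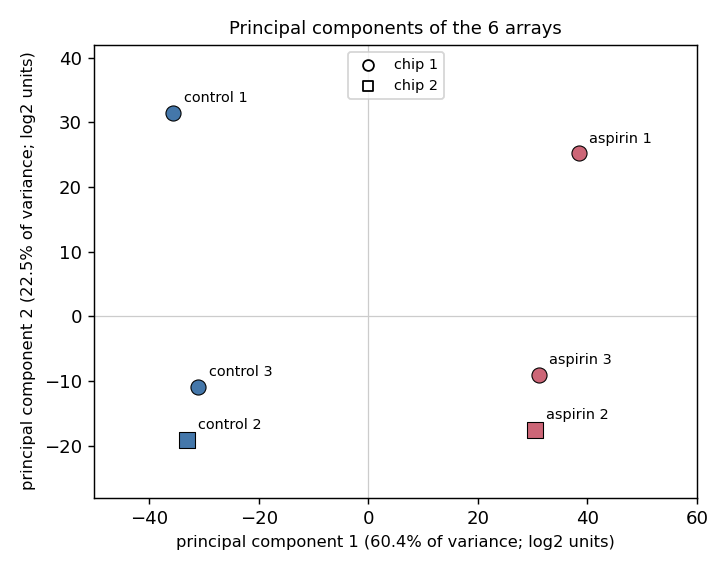
The 6 arrays on the first and second principal components of the normalized log2 signals, both axes in log2 units, with control arrays in blue, aspirin arrays in red, circles for chip 1 and squares for chip 2. The control arrays lie between -35.7 and -31.1 on the first component and the aspirin arrays between 30.5 and 38.4, and both replicate 1 arrays lie at 25.2 and 31.5 on the second, apart from the other 4.

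The gene that rose most with aspirin was GDF15, a secreted cytokine of the TGF-beta superfamily induced by cell stress. It changed by 4.34 ± 0.19 on the log2 scale (SE, n = 3 per group, adjusted p = 2.61e-05), a 20.3-fold rise from a level of 5.42 ± 0.31 (SD) to 9.76 ± 0.20. With the background estimated from all listed genes, below called the all-gene background, its rise was 2.27, below that of the keratin KRT80 (2.47). The gene that fell most, KIF20A, a kinesin of late mitosis, went from 10.31 ± 0.17 to 6.07 ± 0.70 (-4.24 ± 0.31, adjusted p = 0.000227). FGFBP1, a secreted protein that binds fibroblast growth factors, changed by -4.23 ± 0.16 (adjusted p = 2.61e-05) and TGM1, the transglutaminase that cross-links the envelope of keratinocytes, by -4.00 ± 0.17 (adjusted p = 2.61e-05), or -1.62 with the all-gene background. In that setting KIF20A changed by -2.96 and FGFBP1 by -4.06, so their order reversed. All changes below are log2 fold changes, aspirin minus control, ± SE, from 3 arrays per group, and adjusted p is limma's with Benjamini-Hochberg adjustment.

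Of 15128 genes tested, 3059 (20.2%) passed an adjusted p under 0.05, 1589 of them higher with aspirin and 1470 lower. 910 genes changed at least 2-fold, 388 upward and 522 downward, against 352 with the all-gene background. Of 124 named genes past the threshold, 70 had a change over 1.5 times smaller there. Changes of at least 2 log2 units were found for 19 genes upward and 95 downward. The arrays of both groups did not overlap for 5864 genes (38.8%), where chance gives 10%, and for 3054 of the 3059 genes past the threshold. With the replicate number as a block, 5020 genes passed (2642 higher, 2378 lower), and these held all 3059 genes called without it. With the chip as a block 3374 genes passed, and on the chip 1 arrays alone 896. All 896 of these moved the same way in the chip 2 pair. The count was 1879 without control replicate 3, 1771 without aspirin replicate 3 and 452 without both. Without both replicate 1 arrays it was 3029, 2406 of them shared with the fit to all 6 arrays.

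Among the 15 named genes with the largest rises were the keratins KRT86 (2.96 ± 0.57), KRT80 (2.71 ± 0.28) and KRT75 (2.57 ± 0.16). KRT86 belongs to a group of near-identical hair keratin genes, so its value is uncertain. The monooxygenase CYP1A1, a target of the aryl hydrocarbon receptor, rose by 2.43 ± 0.19 and was above background on 2 of 3 control arrays. HBEGF, a ligand of the EGF receptor, rose by 2.28 ± 0.38, the membrane protease ADAM8 by 2.47 ± 0.26, the receptor tyrosine kinase MERTK by 2.22 ± 0.15 and RRAGD, a GTPase that relays amino acid supply to mTORC1, by 2.33 ± 0.22. KHDRBS3, ASGR1, AKAP12, RNU86, CAPN5 and GRAMD1A completed the group with changes from 2.02 to 2.47. RRAGD and CAPN5 were above background on 1 of 3 control arrays. Adjusted p of these 15 genes reached at most 0.00885, for KRT86. Without both replicate 3 arrays the calls of KRT86, HBEGF and GRAMD1A were lost (adjusted p = 0.0897, 0.0582 and 0.0544). With the all-gene background most of these rises were much smaller. MERTK then rose by 0.24, RRAGD by 0.29, CYP1A1 by 0.33, CAPN5 by 0.17 and ASGR1 by 0.39, all still past the threshold. So were KRT75 (1.39), KHDRBS3 (0.68), ADAM8 (0.49), AKAP12 (0.32) and RNU86 (0.23). KRT86 lost its call there (1.73, adjusted p = 0.0713), while HBEGF (2.29) and KRT80 were little altered.

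Most of the 15 largest falls were of genes of mitosis. Besides KIF20A they included the spindle proteins DLGAP5 (-3.81 ± 0.36), FAM83D (-3.41 ± 0.17) and HMMR (-3.07 ± 0.27), cyclin B1 (CCNB1, -3.40 ± 0.15), the centromeric histone CENPA (-3.36 ± 0.26), the kinesin KIF2C (-3.10 ± 0.34), CDKN3 (-3.33 ± 0.42) and CDCA3 (-3.28 ± 0.21). BIRC5, which encodes survivin, an inhibitor of apoptosis that also acts in chromosome segregation, changed by -3.36 ± 0.19 (adjusted p = 0.000103) and was above background on 2 of 3 aspirin arrays. Outside the cell cycle, the largest falls besides FGFBP1 and TGM1 were those of the small GTPase RRAD (-3.41 ± 0.48), the collagenase MMP13 (-3.12 ± 0.23) and CLCA2 (-3.11 ± 0.23). The highest adjusted p of these 15 genes was 0.00229, for RRAD. Its call was lost with the all-gene background (-1.29, adjusted p = 0.231) and with an ordinary two-sample test (adjusted p = 0.0582). Smaller falls in the former setting, all past the threshold, were those of CCNB1 (-1.23), BIRC5 (-0.83), MMP13 (-0.71), CENPA (-0.96), CDCA3 (-0.93), KIF2C (-1.31), HMMR (-1.44), FAM83D (-2.06) and CLCA2 (-1.99).

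**Figure D2:**
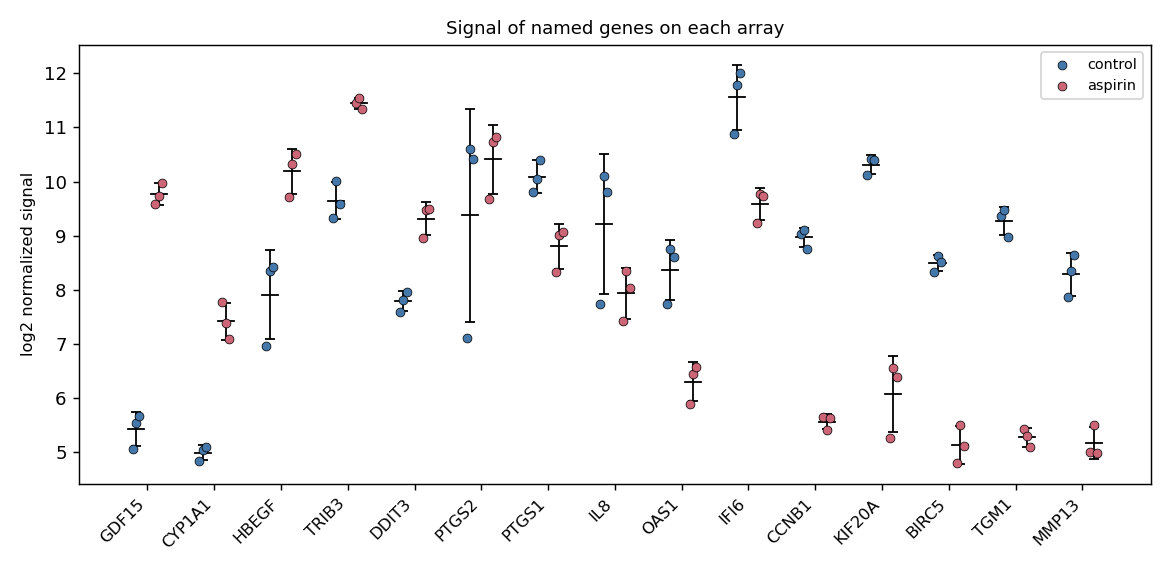
Log2 normalized signal of 15 named genes on each array, control in blue and aspirin in red, with bars for the mean and SD of 3 arrays. GDF15 rose from a mean of 5.42 to 9.76 and CCNB1 fell from 8.97 to 5.57, while the control arrays of PTGS2 span 7.11 to 10.61.

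All 34 genes of the list for mitosis and the G2/M transition fell, with a list median of -2.65, and all 34 fell when adjusted over the list alone. Cyclin B1 had the lowest adjusted p (2.61e-05), followed by the centromere motor CENPE (-2.78 ± 0.14, adjusted p = 5.39e-05), BIRC5 and the mitotic kinase PLK1 (-2.46 ± 0.15, adjusted p = 0.000123). MKI67, the Ki-67 proliferation marker, named after its values were seen, was above background on all control arrays and on no aspirin array and was at least 2.09-fold lower (adjusted p = 0.00106). Against all other genes, camera with its preset correlation gave an adjusted p of 2.79e-31 for the list (adjusted p = 0.379 with an estimated correlation). The median was -2.74 on chip 1 and -2.43 in the chip 2 pair (adjusted p = 2.39e-28 with the chip as a block). The all-gene background gave a median of -1.47 (adjusted p = 2.58e-25). CENPE changed by -0.93 and PLK1 by -0.35 there. The list also passed with the preset correlation in 7 of 9 other splits of the 6 arrays that mix treated and untreated ones (adjusted p down to 5.48e-11). Such splits keep part of the aspirin difference between their groups, so they are not a reference without an effect.

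Of 32 genes of DNA replication and S phase tested, 1 rose, 12 fell and 19 did not pass, with 2 rising and 17 falling when adjusted over the list alone. RRM2, the regulated subunit of ribonucleotide reductase, changed by -2.32 ± 0.20 (adjusted p = 0.000465) and was above background on 1 of 3 aspirin arrays. The replication factor GINS4 (-1.47 ± 0.22, adjusted p = 0.00307), on 2 of 3 aspirin arrays, the flap endonuclease FEN1 (-1.04 ± 0.18, adjusted p = 0.00558) and thymidylate synthase (TYMS, -1.81 ± 0.34, adjusted p = 0.00817) fell as well. The member that rose, named after its values were seen, was cyclin E1, CCNE1 (0.69 ± 0.14, adjusted p = 0.0106). The list median was -0.71 (camera adjusted p = 4.68e-06; adjusted p = 0.756 with an estimated correlation and 0.102 with fry), with -0.76 on chip 1 and -0.52 in the chip 2 pair (adjusted p = 5.39e-06 with the chip as a block). With the replicate block, 2 members rose and 23 fell. The median shrank most with the all-gene background, to -0.25 (adjusted p = 9.12e-06). RRM2 changed by -0.26 and GINS4 by -0.12 in that setting.

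Among cell cycle regulators chosen for naming beforehand, CCND1, which encodes cyclin D1, had a difference of 0.31 ± 0.14 (adjusted p = 0.159) and MYC one of 0.44 ± 0.18 (adjusted p = 0.127), neither past the threshold. CDKN1A, the cyclin-dependent kinase inhibitor p21, missed the filter on detection values, although its normalized signal was 10.03 ± 0.20 (SD) in controls and 10.64 ± 0.29 with aspirin. Its difference of 0.61 had an adjusted p of 0.0930 with no filter and of 0.0450 with a filter on the signal itself, an alternative chosen after the data were seen. CCND1 passed with a trended and robust variance prior (adjusted p = 0.0497).

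Of 33 interferon-stimulated genes tested, 0 rose, 19 fell and 14 did not pass, with 25 falling and 0 rising when adjusted over the list alone. SAMD9, an antiviral factor, had the lowest adjusted p (-1.89 ± 0.16, adjusted p = 0.000379), followed by the oligoadenylate synthetase OAS1 (-2.07 ± 0.29, adjusted p = 0.00230), IFI6 (-1.98 ± 0.29, adjusted p = 0.00304) and a second such synthetase, OAS3 (-1.71 ± 0.26, adjusted p = 0.00325). The list had a median of -1.16 and its camera adjusted p 8.21e-11 (adjusted p = 0.756 with an estimated correlation and 0.0812 with fry). It was -1.04 on chip 1, -1.28 in the chip 2 pair (adjusted p = 1.97e-10 with the chip as a block) and -0.76 with the all-gene background. Among the interferon genes named here, the calls of OAS1 and OAS3 were lost in that setting (adjusted p = 0.0638 and 0.0708). Relative to the mean of all arrays, the median level of the list was -0.09, 0.96 and 0.71 on controls 1 to 3. On aspirin arrays 1 to 3 it was -0.93, -0.36 and -0.33. Control replicate 1 thus lay closer to aspirin replicates 2 and 3 than to the other controls.

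Of the direct targets of aspirin, PTGS1, the constitutive cyclooxygenase, was lower in treated cells, with 10.09 ± 0.30 (SD) in controls and 8.80 ± 0.41 with aspirin (-1.29 ± 0.24, adjusted p = 0.00732). PTGS2, the inducible cyclooxygenase, varied between control arrays by more than the groups differed (9.38 ± 1.96 and 10.41 ± 0.64; 1.03 ± 0.83, adjusted p = 0.429). PTGS2 was higher with aspirin in each replicate pair, at 7.11 and 9.67, 10.61 and 10.74, and 10.41 and 10.82, and did not pass with the replicate block (adjusted p = 0.0933). Its difference was -0.10 without control replicate 1, a fit that keeps the treated array of that pair. In the prostaglandin and eicosanoid pathway 21 genes were tested, of which 6 rose, 4 fell and 11 did not pass, with 6 rising and 6 falling when adjusted over the list alone. ALOX12, a lipoxygenase (1.19 ± 0.15, adjusted p = 0.00160), and PTGES, the inducible prostaglandin E synthase (1.07 ± 0.16, adjusted p = 0.00340), rose, and LTB4R, a leukotriene B4 receptor, fell (-1.11 ± 0.15, adjusted p = 0.00204). The other members that fell, named after their values were seen, were CBR1 (-0.78 ± 0.19, adjusted p = 0.0216, up to 0.0665 without aspirin replicate 2) and TBXAS1, which was not above background on any aspirin array and was at least 1.29-fold lower (adjusted p = 0.0402, up to 0.129 without any 1 of the 6 arrays). The list as a whole did not pass, with a median of -0.03, a mean of 0.10 and a camera adjusted p of 0.999. The call of PTGS1 was lost without both replicate 2 arrays (adjusted p = 0.0594) and without both replicate 3 arrays (adjusted p = 0.0733). It was also lost with an ordinary two-sample test of all 6 arrays (adjusted p = 0.0758). ALOX12 rose by 0.47 and LTB4R changed by -0.29 with the all-gene background.

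Few NF-kB targets and cytokines passed. RELB, an NF-kB subunit (1.34 ± 0.19, adjusted p = 0.00227), and BCL3, a nuclear co-regulator of NF-kB (0.88 ± 0.21, adjusted p = 0.0229), rose, and the neutrophil chemokine CXCL1 fell (-1.83 ± 0.41, adjusted p = 0.0159). Of 26 tested, 2 rose, 1 fell and 23 did not pass, with 2 rising and 1 falling when adjusted over the list alone, and the list median was -0.15 (camera adjusted p = 0.645). IL8, the chemokine now named CXCL8, had a difference of -1.28 ± 0.56 and did not pass (adjusted p = 0.146), nor did SOD2, a mitochondrial superoxide dismutase (-0.58 ± 0.18, adjusted p = 0.0514). In the fit with the replicate block IL8 and SOD2 passed as lower (adjusted p = 0.0112 and 0.0404), and 8 members rose and 11 fell. Without both replicate 1 arrays 4 rose and 12 fell (median -0.42, adjusted p = 0.0704). The call of CXCL1 was lost without control replicate 2 or 3 or aspirin replicate 3 (adjusted p up to 0.0602) and that of BCL3 without control replicate 2 or aspirin replicate 1 or 3 (adjusted p up to 0.0812). Both were also lost with the all-gene background, CXCL1 at a much smaller difference (-0.43, adjusted p = 0.125) and BCL3 at a similar one (0.81, adjusted p = 0.0639). RELB kept its call there at a smaller value (0.31). IL8 passed without control replicate 1 (-2.01, adjusted p = 0.00255), as did SOD2 (-0.68, adjusted p = 0.0404). SOD2 passed also without aspirin replicate 1 (-0.72, adjusted p = 0.0272) and with other normalizations (adjusted p = 0.0232 with median scaling and 0.0318 with cyclic loess).

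Of 26 genes of the ATF4 and amino acid response tested, 10 rose, 1 fell and 15 did not pass, with 12 rising and 2 falling when adjusted over the list alone. The pseudokinase TRIB3 (1.80 ± 0.19, adjusted p = 0.000780), the glutathione-degrading CHAC1 (1.43 ± 0.17, adjusted p = 0.00119), above background on 1 of 3 control arrays, and asparagine synthetase (ASNS, 1.13 ± 0.15, adjusted p = 0.00195) were higher with aspirin, and PSPH, the last enzyme of serine synthesis, was lower (-0.75 ± 0.13, adjusted p = 0.00583). The median of the list was 0.40 and the camera adjusted p 0.00125 (adjusted p = 0.285 with an estimated correlation). The median was 0.37 on chip 1 and 0.41 in the chip 2 pair (adjusted p = 0.00120 with the chip as a block). With the all-gene background it was 0.23 (adjusted p = 0.00138). CHAC1 rose by only 0.09 there and PSPH changed by -0.23, both past the threshold.

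In the unfolded protein response of the endoplasmic reticulum, 7 of 22 genes rose and 0 fell, the same counts as when adjusted over the list alone. They included the stress transcription factor DDIT3 (1.52 ± 0.19, adjusted p = 0.00137), HERPUD1 (1.03 ± 0.16, adjusted p = 0.00401), which acts in the degradation of misfolded proteins, the chaperone DNAJB9 (0.90 ± 0.16, adjusted p = 0.00660) and PPP1R15A (0.92 ± 0.21, adjusted p = 0.0165), the phosphatase subunit that restores translation. The list did not pass as a set (median 0.14, camera adjusted p = 0.160). PPP1R15A lost its call without aspirin replicate 2 or 3 (adjusted p up to 0.0583).

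Targets of p53, GDF15 among them, did not pass as a group, and of 22 tested 4 rose, 1 fell and 17 did not pass, with 4 rising and 2 falling when adjusted over the list alone. CDKN1A is on the list but was not among the 22, because it missed the detection filter. Its difference was 0.61 (limma adjusted p = 0.0930 with no filter and 0.0450 with a filter on the signal itself). SESN2, a stress-induced regulator of mTORC1 (1.19 ± 0.23, adjusted p = 0.00829; above background on 2 of 3 control arrays), and CCNG1, cyclin G1 (0.79 ± 0.20, adjusted p = 0.0239), rose and GADD45A, a growth arrest gene, fell (-0.62 ± 0.14, adjusted p = 0.0161). The other member that rose, named after its values were seen, was RRM2B (0.83 ± 0.21, adjusted p = 0.0272, up to 0.0876 without control replicate 1 or 3 or aspirin replicate 1 or 2). The list median was 0.02, or 0.00 with members below background in a group at their bound (camera adjusted p = 0.801). CCNG1 lost its call without control replicate 2 or 3 or aspirin replicate 1 or 3 (adjusted p up to 0.0750) and GADD45A without control replicate 2 or aspirin replicate 2 or 3 (adjusted p up to 0.0652). The all-gene background reduced SESN2 and ended its call (0.10, adjusted p = 0.0503), and ended that of CCNG1 (0.62, adjusted p = 0.0956). GADD45A kept its call there at -0.37.

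NRF2 and oxidative stress genes split: of 25 tested, 6 rose, 5 fell and 14 did not pass, with 6 rising and 9 falling when adjusted over the list alone. The aldo-keto reductase AKR1B10 (-2.28 ± 0.17, adjusted p = 0.000229) and the carbonyl reductase CBR3 (-1.03 ± 0.14, adjusted p = 0.00228) fell, and GCLC, the catalytic subunit of glutamate-cysteine ligase (1.06 ± 0.14, adjusted p = 0.00191), and thioredoxin reductase 1 (TXNRD1, 0.79 ± 0.13, adjusted p = 0.00524) rose. The other members that fell, named after their values were seen, were CBR1 (-0.78 ± 0.19, adjusted p = 0.0216, up to 0.0665 without aspirin replicate 2), GPX2 (-1.23 ± 0.31, adjusted p = 0.0251, up to 0.0534 without control replicate 1) and UGDH (-0.46 ± 0.14, adjusted p = 0.0442, up to 0.144 without control replicate 2 or 3 or any 1 aspirin array). Its members had a median of -0.03 (camera adjusted p = 0.645). Of 11 aryl hydrocarbon receptor targets, 1 rose, 2 fell and 8 did not pass, the same as when adjusted over the list alone. CYP1A1 rose (adjusted p = 0.000286), the glucuronosyltransferase UGT1A6 (-0.69 ± 0.13, adjusted p = 0.00868) and the aldehyde dehydrogenase ALDH3A1 (-0.95 ± 0.23, adjusted p = 0.0203) fell, and NQO1 did not pass (-0.35 ± 0.14, adjusted p = 0.113). The median of that list was -0.26 and its mean 0.04 (camera adjusted p = 0.645). ALDH3A1 lost its call without control replicate 2 or aspirin replicate 1 or 3 (adjusted p up to 0.0631) and, at a much smaller difference, with the all-gene background (-0.12, adjusted p = 0.129). AKR1B10 changed by -0.41 and CBR3 by -0.54 there, both past the threshold. NQO1 passed as lower with no background correction (adjusted p = 0.0485).

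By limma's test, none of 19 heat shock genes passed, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05 (median -0.04, camera adjusted p = 0.645). The small heat shock proteins CRYAB (-0.58 ± 0.18, adjusted p = 0.0516) and HSPB8 (-0.97 ± 0.31, adjusted p = 0.0585) and HSPA6 (-0.51 ± 0.17, adjusted p = 0.0636; above background on 1 of 3 aspirin arrays) had the lowest p values with DNAJB1 (0.33 ± 0.16, adjusted p = 0.186). With the replicate block CRYAB, HSPB8 and HSPA6 passed as lower (adjusted p = 0.0312, 0.00224 and 0.0244). Of 6 metallothioneins, small metal-binding proteins of near-identical sequence and therefore uncertain, MT1E fell (-0.97 ± 0.25, adjusted p = 0.0255), as it did when adjusted over the list alone, and the other members did not pass (list median -0.08, camera adjusted p = 0.645). The others with the lowest p values were MT1G (0.75 ± 0.52), MT1X (-0.14 ± 0.15) and MT1F (-0.21 ± 0.53). In the fit with the replicate block 1 member rose, MT1G (adjusted p = 0.00283), and 1 fell, and MT1E lost its call without control replicate 2 or 3 (adjusted p up to 0.0871) and with the all-gene background (-1.29, adjusted p = 0.0875). HSPB8 passed as lower without control replicate 1 (-1.15, adjusted p = 0.0419) or aspirin replicate 2 (-1.22, adjusted p = 0.0370), HSPA6 without aspirin replicate 1 (-0.68, adjusted p = 0.0274), and CRYAB with median scaling (adjusted p = 0.0474) and cyclic loess (adjusted p = 0.0444). MT1G passed as higher without both replicate 1 arrays (0.77, adjusted p = 0.0119).

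Of 24 genes of keratinocyte terminal differentiation tested, 1 rose, 6 fell and 17 did not pass, with 2 rising and 8 falling when adjusted over the list alone. TGM1 fell (adjusted p = 2.61e-05), as did both calprotectin subunits, S100A9 (-1.74 ± 0.18, adjusted p = 0.000801) and S100A8 (-1.79 ± 0.22, adjusted p = 0.00152), and KRT13, a keratin of differentiating mucosal epithelium (-2.05 ± 0.31, adjusted p = 0.00353). A kallikrein protease named after its values were seen, KLK6 (1.50 ± 0.26, adjusted p = 0.00607), rose. The median of the list was -0.56 (camera adjusted p = 0.00730; adjusted p = 0.756 with an estimated correlation and 0.0812 with fry), -0.61 on chip 1 and -0.33 in the chip 2 pair (adjusted p = 0.0120 with the chip as a block). In replicate pairs 1 to 3 the median was -0.91, -0.33 and -0.16. Without control replicate 1 the median was -0.06 and the call was lost (adjusted p = 0.161). That fit keeps the treated array of the pair. Without both replicate 1 arrays the list passed by camera (median -0.19, adjusted p = 0.0413). With the replicate block 2 members rose and 10 fell. The call was also lost with genes detected on all 6 arrays at a detection p under 0.01 (adjusted p = 0.0751). The all-gene background gave a median of -0.21 (adjusted p = 0.0301).

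Of 12 stress keratins and genes of epidermal hyperproliferation, 0 rose, 3 fell and 9 did not pass, with 4 falling and 0 rising when adjusted over the list alone. The serpins SERPINB3 (-2.47 ± 0.23, adjusted p = 0.000611) and SERPINB4, protease inhibitors of near-identical sequence and therefore uncertain, fell. SERPINB4 was not above background on any aspirin array and was at least 3.78-fold lower (adjusted p = 0.000554). KRT6C, which is near-identical to KRT6A and KRT6B and therefore uncertain, fell by less (-0.63 ± 0.16, adjusted p = 0.0300), and S100A2 did not pass (-0.63 ± 0.20, adjusted p = 0.0588) but did with the replicate block (adjusted p = 0.00616), where 1 member rose and 5 fell. The list median was -0.33 (camera adjusted p = 0.0347; adjusted p = 0.756 with an estimated correlation and 0.0778 with fry), with -0.23 on chip 1 and -0.36 in the chip 2 pair (adjusted p = 0.0460 with the chip as a block, 0.0965 on chip 1 alone). Without aspirin replicate 2 or aspirin replicate 3 the list did not pass (adjusted p = 0.0933 and 0.111), nor with cyclic loess normalization (adjusted p = 0.0642). Its median with the all-gene background was -0.17 (adjusted p = 0.0392). KRT6C lost its call in that setting (-0.65, adjusted p = 0.0549) and without any 1 control array or aspirin replicate 2 or 3 (adjusted p up to 0.101). The values of SERPINB3 and SERPINB4 were -0.93 and -0.20 with the all-gene background, both past the threshold, so the bound for SERPINB4 does not hold there. S100A2 passed without control replicate 3 (-0.79, adjusted p = 0.0488) or aspirin replicate 1 (-0.78, adjusted p = 0.0379) and with median scaling (adjusted p = 0.0442) and cyclic loess (adjusted p = 0.0405).

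Basal keratinocyte and hemidesmosome genes changed in both directions. Of 19 tested, 6 rose, 5 fell and 8 did not pass, with 6 rising and 7 falling when adjusted over the list alone. Integrin alpha 2 (ITGA2) rose (1.71 ± 0.17, adjusted p = 0.000703), while integrin alpha 6 (ITGA6, -1.47 ± 0.16, adjusted p = 0.000910) and the basal keratins KRT14 (-1.27 ± 0.15, adjusted p = 0.00125) and KRT5 (-1.27 ± 0.16, adjusted p = 0.00170) fell. The other members that fell, named after their values were seen, were SOX2 (-1.18 ± 0.23, adjusted p = 0.00892) and FERMT1 (-0.49 ± 0.14, adjusted p = 0.0413, up to 0.121 without any 1 of the 6 arrays). Its members had a median of -0.14 (camera adjusted p = 0.645). ITGA6 changed by -0.34 with the all-gene background.

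In the epithelial-mesenchymal transition list, 2 of 18 genes fell and 0 rose, with 1 falling when adjusted over the list alone. LOX, which cross-links collagen and elastin (-2.44 ± 0.25, adjusted p = 0.000745), and the epithelial integrin ITGB6 (-0.61 ± 0.17, adjusted p = 0.0395) fell, and CYR61, now named CCN1 (-0.70 ± 0.26, adjusted p = 0.100), and the matrix glycoprotein THBS1 (-1.05 ± 0.51, adjusted p = 0.188) did not pass. In the fit with the replicate block THBS1 passed as lower (adjusted p = 0.00512) and 4 members fell. The list did not pass (median -0.22, camera adjusted p = 0.266), but without both replicate 1 arrays it did, with 8 members lower (median -0.32, adjusted p = 0.00253). ITGB6 lost its call without control replicate 2 or 3 or any 1 aspirin array (adjusted p up to 0.124), and nearly all of its fall with the all-gene background (-0.07, adjusted p = 0.137). Without control replicate 1 THBS1 (-1.64, adjusted p = 0.0152) and CYR61 (adjusted p = 0.00825) passed as lower, as they did without both replicate 1 arrays (adjusted p = 0.00395 and 0.00316).

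Of 21 matrix proteases and their inhibitors, 1 rose, 5 fell and 15 did not pass, the same as when adjusted over the list alone. MMP13 fell (adjusted p = 0.000227), as did stromelysin 1 (MMP3, -1.76 ± 0.30, adjusted p = 0.00546) and the membrane sheddase ADAM9 (-1.11 ± 0.17, adjusted p = 0.00400). Named after their values were seen, ADAMTS1 (-0.57 ± 0.17, adjusted p = 0.0477, up to 0.157 without control replicate 2 or 3 or aspirin replicate 1 or 3), above background on 1 of 3 aspirin arrays, fell as well and PLAU (1.23 ± 0.37, adjusted p = 0.0468, up to 0.126 without control replicate 3 or any 1 aspirin array), the urokinase plasminogen activator, rose. Matrilysin (MMP7) was not above background on any aspirin array and was at least 4.35-fold lower (adjusted p = 0.000960). The list as a whole did not pass (median -0.15, camera adjusted p = 0.266), and with the replicate block 4 members rose and 9 fell. With the all-gene background the calls of MMP3 and MMP7 were lost (adjusted p = 0.101 and 0.0584). Their differences were -0.32 and -0.26, far inside the bound for MMP7, and ADAM9 kept its call at -0.23.

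Of 7 tested markers of fibroblasts, a cell type other than that of the line, 0 rose, 5 fell and 2 did not pass, with 6 falling when adjusted over the list alone. The proteoglycan lumican (LUM) fell (-2.88 ± 0.34, adjusted p = 0.00128), as did the collagen chain COL1A1 (-1.23 ± 0.22, adjusted p = 0.00709) and the calcium-binding S100A4 (-1.71 ± 0.34, adjusted p = 0.00994). The other that fell, named after its values were seen, was COL1A2 (-1.04 ± 0.24, adjusted p = 0.0193, up to 0.0697 without control replicate 2 or 3 or aspirin replicate 1 or 2). Decorin (DCN) was not above background on any aspirin array and was at least 3.61-fold lower (adjusted p = 0.000906). The median of the list was -1.23 (camera adjusted p = 6.32e-05; adjusted p = 0.379 with an estimated correlation), -0.97 on chip 1 and -1.41 in the chip 2 pair (adjusted p = 0.000157 with the chip as a block). In replicate pairs 1 to 3 the median was -0.74, -1.41 and -1.30. With the all-gene background it was -0.24 (adjusted p = 0.00471), and LUM, COL1A1 and S100A4 lost their calls there (adjusted p = 0.0663, 0.0561 and 0.224). DCN kept its call there at -0.19, which is inside its bound.

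Of 5 leukocyte and blood markers that could be tested, CD14, a lipopolysaccharide co-receptor, fell (-0.94 ± 0.24, adjusted p = 0.0266), as it did when adjusted over the list alone, and FCGR3A (-0.10 ± 0.13), CD79A (-0.09 ± 0.12) and HBA2 (0.06 ± 0.25) did not pass (list median -0.09, camera adjusted p = 0.606). FCGR3A and CD79A were above background on 1 of 3 aspirin arrays and HBA2 on 2 of 3 arrays of each group. CD14 lost its call without aspirin replicate 2 or 3 (adjusted p up to 0.0945) and with the all-gene background (-0.48, adjusted p = 0.159). Of 12 melanocyte and endothelial markers only TEK (-0.36 ± 0.15, adjusted p = 0.118; above background on 1 of 3 aspirin arrays) and SILV, now named PMEL (-0.11 ± 0.17, adjusted p = 0.705; on 2 of 3 arrays of each group), were tested, and neither passed over all genes or adjusted over the list alone. With the replicate block TEK passed as lower (adjusted p = 0.0487). That list was too short for a set test.

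Of 22 glycolysis and hypoxia genes tested, 0 rose, 12 fell and 10 did not pass, with 1 rising and 13 falling when adjusted over the list alone. The glycolytic enzymes PGK1 (-1.14 ± 0.14, adjusted p = 0.00131) and PGAM1 (-1.37 ± 0.17, adjusted p = 0.00134) and the stress-responsive NDRG1 (-0.71 ± 0.12, adjusted p = 0.00594) were lower. Carbonic anhydrase 9 (CA9), a hypoxia marker, was not above background on any aspirin array and was at least 1.96-fold lower (adjusted p = 0.00108). The list median was -0.52 and the camera adjusted p 6.32e-05 (adjusted p = 0.249 with an estimated correlation). The median was -0.63 on chip 1 and -0.50 in the chip 2 pair (adjusted p = 4.91e-05 with the chip as a block). The fall of CA9 was -0.09 with the all-gene background, past the threshold but far inside its bound.

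Of 34 subunits of the mitochondrial respiratory chain tested, 0 rose, 4 fell and 30 did not pass, and 1 fell when adjusted over the list alone. The succinate dehydrogenase subunit SDHC (-0.71 ± 0.13, adjusted p = 0.00866), the complex I subunit NDUFB8 (-0.55 ± 0.17, adjusted p = 0.0481) and the ATP synthase subunit ATP5A1, now named ATP5F1A (-0.48 ± 0.13, adjusted p = 0.0384), passed. In the fit with the replicate block 9 members fell. Its members had a median of -0.18 (camera adjusted p = 0.00475; adjusted p = 0.756 with an estimated correlation), -0.22 on chip 1 and -0.18 in the chip 2 pair (adjusted p = 0.00361 with the chip as a block). The list did not pass without both replicate 1 arrays (median -0.13, adjusted p = 0.0868), and NDUFB8 lost its call without any 1 control array or aspirin replicate 1 or 3 (adjusted p up to 0.127) and ATP5A1 without control replicate 2 or 3 or any 1 aspirin array (adjusted p up to 0.129). NDUFB8 was also lost with the all-gene background (-0.60, adjusted p = 0.0783).

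Among 24 genes of cholesterol biosynthesis and uptake, 2 rose, 3 fell and 19 did not pass, the same as when adjusted over the list alone. Mevalonate decarboxylase (MVD) rose (0.96 ± 0.16, adjusted p = 0.00548), while the acetyl-CoA acetyltransferase ACAT2 fell (-0.65 ± 0.14, adjusted p = 0.0127). The other that rose, named after its values were seen, was TM7SF2 (1.20 ± 0.28, adjusted p = 0.0193, up to 0.0719 without control replicate 2 or 3 or aspirin replicate 1 or 3). The median was 0.07 (camera adjusted p = 0.920). With the replicate block 4 rose and 4 fell. MVD rose by 0.19 with the all-gene background.

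Of 12 fatty acid synthesis genes, 2 rose, 1 fell and 9 did not pass, with 3 rising and 1 falling when adjusted over the list alone. The phosphatidate phosphatase LPIN1 (1.64 ± 0.20, adjusted p = 0.00131) and the glucose-responsive transcription factor MLXIPL (1.11 ± 0.21, adjusted p = 0.00813) rose and the desaturase FADS1 fell (-0.98 ± 0.25, adjusted p = 0.0284). ACSL3, a fatty acyl-CoA ligase, did not pass (0.50 ± 0.16, adjusted p = 0.0637) but did with the replicate block (adjusted p = 0.0241), where 5 rose and 3 fell. Of 20 genes of fatty acid oxidation and PPAR targets, 4 rose, 2 fell and 14 did not pass, the same as when adjusted over the list alone. The rises were those of the lipid droplet protein PLIN2 (1.66 ± 0.21, adjusted p = 0.00170), the acyl-CoA dehydrogenase ACADVL (0.82 ± 0.14, adjusted p = 0.00530), CPT1A, which carries fatty acids into mitochondria (0.84 ± 0.15, adjusted p = 0.00686), and ECH1 (1.07 ± 0.19, adjusted p = 0.00709). The falls, named after their values were seen, were those of FABP5 (-1.46 ± 0.38, adjusted p = 0.0290, up to 0.0860 without any 1 aspirin array) and ETFDH (-0.61 ± 0.17, adjusted p = 0.0338, up to 0.112 without any 1 control array or aspirin replicate 1 or 3). Neither list passed as a set (medians 0.10 and 0.17, camera adjusted p = 0.645 for both). FADS1 lost its call without any 1 control array or aspirin replicate 3 (adjusted p up to 0.0712). MLXIPL was lost with the all-gene background (0.18, adjusted p = 0.0505). LPIN1 rose by 1.05, PLIN2 by 0.31 and CPT1A by 0.09 in that setting, and FADS1 changed by -0.32. ACSL3 passed with no background correction (adjusted p = 0.0453).

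Of 23 genes of the EGFR and MAPK response tested, 6 rose, 2 fell and 15 did not pass, with 8 rising and 2 falling when adjusted over the list alone. HBEGF (adjusted p = 0.00539) and the ETS transcription factors ETV4 (1.18 ± 0.23, adjusted p = 0.00885) and ETV5 (1.68 ± 0.34, adjusted p = 0.0115) rose, and the immediate early gene FOS fell (-1.81 ± 0.16, adjusted p = 0.000465). So did a member named after its values were seen, DUSP1 (-0.69 ± 0.16, adjusted p = 0.0190, up to 0.0523 without aspirin replicate 1 or 3). In the fit with the replicate block 13 members rose and 3 fell. The median of the list was 0.47 (camera adjusted p = 0.0313; adjusted p = 0.756 with an estimated correlation and 0.187 with fry), 0.47 on chip 1 and 0.34 in the chip 2 pair (adjusted p = 0.0413 with the chip as a block). The call was lost without control replicate 1, aspirin replicate 2 or aspirin replicate 3 (adjusted p = 0.116, 0.0917 and 0.0508), with array weights (0.0675) and with stricter detection filters (0.105 and 0.192). Without both replicate 1 arrays the list passed by camera (median 0.34, adjusted p = 0.0413). The median was smaller with the all-gene background, at 0.20 (adjusted p = 0.0350), and ETV5 lost its call there (0.52, adjusted p = 0.0515). ETV4 rose by 0.32 and FOS changed by -0.29 in that setting.

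Of 13 Wnt and beta-catenin targets, 1 rose, 2 fell and 10 did not pass, with 1 rising and 3 falling when adjusted over the list alone. The ubiquitin ligase RNF43, a feedback inhibitor of Wnt receptors, rose (0.81 ± 0.14, adjusted p = 0.00586), and the secreted Wnt inhibitor DKK1 (-0.57 ± 0.12, adjusted p = 0.0137) and the transcription factor ASCL2 (-0.69 ± 0.16, adjusted p = 0.0204) fell. The adhesion receptor CD44 did not pass (-0.46 ± 0.15, adjusted p = 0.0603) but did with the replicate block (adjusted p = 0.0235), where 3 rose and 4 fell. The median was 0.25, or 0.18 with members below background in a group at their bound (camera adjusted p = 0.645). DKK1 lost its call without control replicate 3 or aspirin replicate 3 (adjusted p up to 0.0545) and ASCL2 without control replicate 2 or 3 or aspirin replicate 3 (adjusted p up to 0.0662). RNF43 rose by 0.08 and ASCL2 changed by -0.42 with the all-gene background. CD44 passed without aspirin replicate 1 (-0.57, adjusted p = 0.0442) and with median scaling (adjusted p = 0.0398) and cyclic loess (adjusted p = 0.0403).

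Of 20 genes of the BCL2 family and caspases, 2 rose, 1 fell and 17 did not pass, the same as when adjusted over the list alone. The initiator caspase CASP9 (0.98 ± 0.15, adjusted p = 0.00374) and the antiapoptotic BCL2L2 (0.84 ± 0.15, adjusted p = 0.00706) rose, and BAD did not pass (0.40 ± 0.16, adjusted p = 0.123). The median was 0.00 (camera adjusted p = 0.852). Among 22 autophagy and lysosome genes, 3 rose, 2 fell and 17 did not pass, the same as when adjusted over the list alone. The sialidase NEU1 (1.35 ± 0.13, adjusted p = 0.000703), WIPI1, which acts in autophagosome formation (0.97 ± 0.12, adjusted p = 0.00172), and the autophagy receptor SQSTM1 (0.92 ± 0.15, adjusted p = 0.00441) rose and the lysosomal galactosidase GLA fell (-0.78 ± 0.14, adjusted p = 0.00684). The median was -0.04 and the mean 0.04 (camera adjusted p = 0.999). CASP9 rose by 0.17 and WIPI1 by 0.50 with the all-gene background, and BAD passed as higher without control replicate 1 (0.55, adjusted p = 0.0389).

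Of 25 ribosome biogenesis genes, 5 rose, 1 fell and 19 did not pass, the same as when adjusted over the list alone. The processing factor RRP12 (1.50 ± 0.19, adjusted p = 0.00174), the helicase DDX21 (0.59 ± 0.13, adjusted p = 0.0153) and the methyltransferase NOP2 (0.55 ± 0.15, adjusted p = 0.0346) rose and NOP58, of the box C/D particles, fell (-0.65 ± 0.18, adjusted p = 0.0373). The other members that rose, named after their values were seen, were RRP9 (0.90 ± 0.27, adjusted p = 0.0470, up to 0.119 without control replicate 2 or 3 or any 1 aspirin array) and GNL3 (0.44 ± 0.13, adjusted p = 0.0482, up to 0.158 without any 1 of the 6 arrays). With the replicate block 8 rose and 3 fell. DDX21 lost its call without control replicate 3 (adjusted p up to 0.0603), NOP2 without control replicate 2 or 3 or any 1 aspirin array (adjusted p up to 0.116) and NOP58 without control replicate 1 or 3 or any 1 aspirin array (adjusted p up to 0.115), and the list did not pass (median 0.09, camera adjusted p = 0.645). NOP58 was lost with the all-gene background as well (-0.85, adjusted p = 0.0788). Of 25 cytosolic ribosomal protein genes none passed by limma's test, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Among the lowest p values of that list were those of RPS3 (0.26 ± 0.13), RPL3 (0.21 ± 0.13) and RPS6 (0.21 ± 0.13; list median 0.07, camera adjusted p = 0.387). By fry the ribosomal protein list passed as higher (adjusted p = 0.0468). RPS3 passed as higher with the all-gene background (adjusted p = 0.0456) and with no background correction (adjusted p = 0.0455).

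Some common reference genes passed the threshold. Of 14 tested, 1 rose, 3 fell and 10 did not pass, with 1 rising and 4 falling when adjusted over the list alone (median -0.16, camera adjusted p = 0.161). By fry the list passed as lower (adjusted p = 0.0141). Besides PGK1, the cyclophilin PPIA (-0.69 ± 0.15, adjusted p = 0.0141) fell, and the transferrin receptor TFRC rose (0.78 ± 0.17, adjusted p = 0.0141). PPIA lost its call without control replicate 3 or aspirin replicate 2 or 3 (adjusted p up to 0.0587). The difference was -0.03 ± 0.13 for actin (ACTB) and -0.14 ± 0.12 for GAPDH, named here after their values were seen, and neither passed. PPIA changed by -0.22 with the all-gene background.

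**Figure D3:**
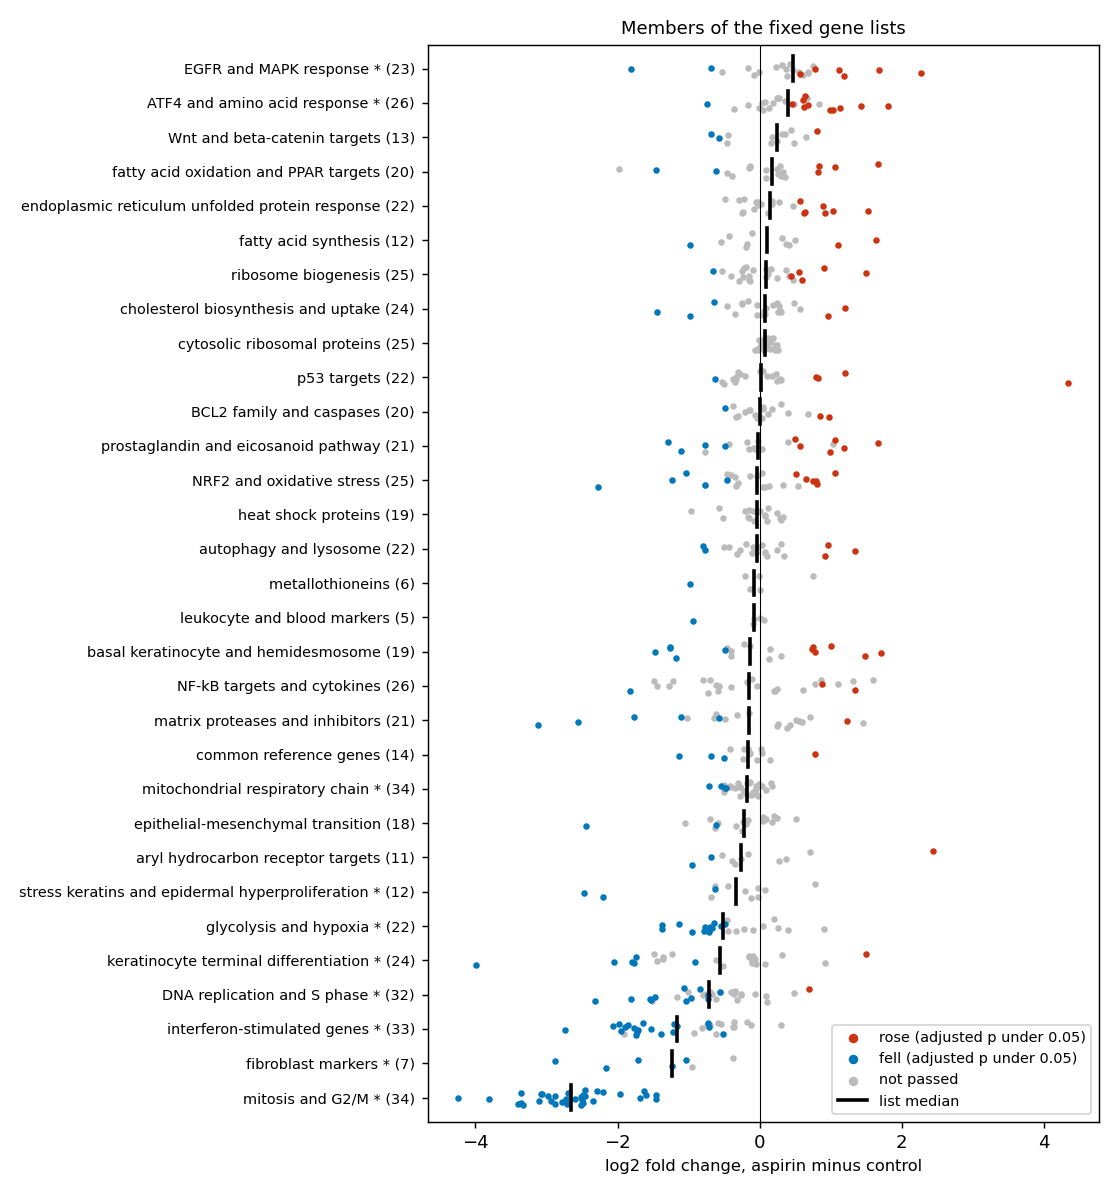
Log2 fold change, aspirin minus control, of each tested member of the fixed gene lists, red where it rose and blue where it fell at an adjusted p under 0.05, grey where it did not pass, with a black bar for the list median, an asterisk for lists past an adjusted p under 0.05 by camera with its preset correlation, and the number of tested members in brackets; members below background in a group are drawn at their fitted value. The list medians run from -2.65 for mitosis to 0.47 for the EGFR and MAPK response.

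Of 31 lists tested against all other genes with camera and its preset correlation, 10 passed, 2 upward and 8 downward, and the same 10 with the replicate or the chip as a block. With an estimated correlation camera called 0 lists, and 4 had an unadjusted p under 0.05, while fry, which tests a list's own genes without comparing them with others, called 7. These included the common reference genes and the cytosolic ribosomal proteins, which camera did not call. In other splits of the 6 arrays into 3 and 3, each mixing treated and untreated arrays, up to 10 lists passed with the preset correlation and limma called 0 genes, with up to 922 at an unadjusted p under 0.05. The aspirin difference widens the spread within such groups and partly remains between them, so neither count measures chance.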

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

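The estimate of the background from all listed genes and the filter on signal were chosen after the data were seen; the other alternatives were planned. Against 3059 genes (1589 higher, 1470 lower), the replicate block gave 5020 genes (2642 higher, 2378 lower), chip 1 arrays only 896 genes (428 higher, 468 lower), an adjusted p under 0.01 1236 genes (607 higher, 629 lower) and an ordinary test 1488 genes (764 higher, 724 lower). Leaving out arrays gave 452 to 3029 genes, 186 to 1531 higher and 266 to 1498 lower, with 1879 without control replicate 3, 1771 without aspirin replicate 3 and 896 without replicate 2, fits with fewer arrays. The fit without replicate 2 holds the same arrays as that of chip 1 only and is not a separate check. The other settings gave 2136 to 4121 genes. Genes changed at least 2-fold, 910 in the reported fit, numbered 324 with no background correction, 488 with an offset of 50, 352 with the background from all listed genes, 532 with an ordinary test and 452 to 943 without arrays. With no background correction or a larger offset a constant stays in the signal, which compresses folds by construction. The estimate from all listed genes instead subtracts a higher background (means of 132 to 175 against 95.4 to 116 intensity units). The ordinary test leaves the folds unchanged and alters only p-values. Other causes were not tested. No called gene changed sign under another background correction or normalization (0 of 3059 by limma), and the share of higher calls ran from 47.0 to 53.1% (51.9% in the reported fit).

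Of the 152 genes under the naming rule 124 passed, all with the same sign under every setting; 97 stayed past the threshold under the settings that kept all arrays, the test and the threshold, 101 in every fit without 1 array and 60 in every fit without arrays, while 25 calls were lost with the background from all listed genes. Genes that changed sign had not passed: over the fits without arrays PTGS2 ranged from -0.10 to 1.64, MT1X from -0.24 to 0.0113, MT1F from -0.74 to 0.32, HBA2 from -0.22 to 0.23 and SILV from -0.24 to 0.00178. Apart from the genes and counts given with it in the report, the replicate block changed no call of a named gene or list. Among lists without such counts, the block gave 6 rising and 8 falling NRF2 genes and 4 rising and 3 falling p53 targets. It gave 4 and 4 of fatty acid oxidation, 3 and 4 of autophagy and 6 and 6 of prostaglandin genes.

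Of the 10 called lists, camera with an estimated correlation called 0 (4 at an unadjusted p under 0.05), fry called 5 of them, and 6 lists passed with detection on all 6 arrays at p under 0.01, where fewer genes are tested. Mitosis, interferon, S phase, glycolysis and ATF4 lists passed in all 25 settings of the data and fit, and the fibroblast list in the 23 where it could be tested, with an adjusted p of at most 0.00990. The respiratory chain list was lost without replicate 1, keratinocyte differentiation in 2 of 25 settings (adjusted p 0.000343 to 0.161), the EGFR list in 7 (0.00351 to 0.192) and stress keratins in 9 (0.00238 to 0.351). The settings count the chip 1 fit and the identical fit without replicate 2 separately, and both are among the 9 of stress keratins. The mean of all probes of a gene was not run, because the table has 1 value per gene. Signal over background limits folds of dim genes, and with 3 arrays per group changes of 0.5 log2 units were called for 8 of 50 simulated genes. That simulation had independent noise and fewer changed genes, so its rate may not hold for these data.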

Other observations

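The tests of gene families, those on the replicate 1 arrays and the background estimate from all listed genes were chosen after results were seen. Families were formed from shared name stems, 181 of them with at least 8 genes tested, and 14 passed by camera with its preset correlation and 0 with an estimated one (adjusted p = 0.768 for each family below). Of 13 regulatory subunits of the proteasome, the complex that degrades ubiquitinated proteins, 6 fell, among them PSMD1 (-1.15 ± 0.16, adjusted p = 0.00226) and PSMD11 (-0.99 ± 0.15, adjusted p = 0.00371; family adjusted p = 0.000977). Of 10 PSMB subunits, which form its catalytic core, 4 fell, among them PSMB2 (-0.82 ± 0.14, adjusted p = 0.00517) and PSMB4 (-0.60 ± 0.13, adjusted p = 0.0137; family adjusted p = 0.0178). The calcium-binding S100A10 (-1.31 ± 0.13, adjusted p = 0.000620) and its annexin partner ANXA2 (-0.75 ± 0.13, adjusted p = 0.00554), a gene with near-identical pseudogenes and therefore uncertain, fell as well.

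Histone genes, whose transcripts are made mainly in S phase, fell in 15 of 32 cases and rose in 2 (family adjusted p = 0.0327). HIST1H4C (-2.37 ± 0.37, adjusted p = 0.00400) and HIST1H2BJ (-1.37 ± 0.17, adjusted p = 0.00148) were lower, while HIST3H2A rose (1.80 ± 0.25, adjusted p = 0.00232); these genes are near-identical in sequence and their values are uncertain. Host genes of small nucleolar RNAs rose in 3 of 10 cases (family adjusted p = 0.0180), among them SNHG5 (1.75 ± 0.19, adjusted p = 0.000960) and SNHG7 (1.37 ± 0.22, adjusted p = 0.00437). Golgins, coiled-coil proteins of the Golgi apparatus, rose in 5 of 9 cases (family adjusted p = 0.0282), among them GOLGA2 (0.88 ± 0.13, adjusted p = 0.00291) and GOLGA5 (0.73 ± 0.14, adjusted p = 0.00839).

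The fibroblast list had a median change of -1.23, which may reflect fibroblasts among the control cultures, the treatment of dim signals, or the line's own genes. Of the 4 abundant fibroblast transcripts COL1A1, COL1A2, COL3A1 and DCN, 3 were detected on all 3 control arrays and COL3A1 was not, which leaves the presence of fibroblasts open; control signals were 211.0 to 350.3 for COL1A1 and 157 to 268 for DCN over a mean background of 101 to 116. 7 of the list's 13 genes could be tested in this line. The planned background corrections and normalizations gave list medians of -1.26 to -0.69, but with the background estimated from all listed genes it was -0.24, so the size of the fall depends on that estimate. The estimate from all listed genes, at 132 to 175 intensity units, lay above the median signal of every array (101.9 to 127.0). The estimate used in the reported fit equals, when rounded, the constants of the deposited matrix. A change in the line's own cells was not tested and stays open.

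The interferon list had a median of -1.16. Its highest median over the 3 replicate pairs was -0.97 and over other background corrections and normalizations -0.76, which argues against 1 pair or the normalization as its source. A slower cell cycle could lower it too, and in the pair with the smallest mitotic fall the interferon median was -1.28. That value had been set to count against this explanation, but the mitotic list fell strongly in every pair (-2.90, -2.43 and -2.57), so no pair shows the interferon genes without it. A slower cell cycle was also predicted to give both lists the same order over the pairs. The order was the reverse, with interferon medians of -0.97, -1.28 and -1.05 in pairs 1 to 3. With 3 pairs, none of them lacking the mitotic fall, this order does not decide the question. An effect of aspirin on these genes and a slower cell cycle cannot be told apart, since every treated array shows both.

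Both replicate 1 arrays stood apart from the others. The same chip would bring replicates 1 and 3 together, but within both groups they correlated less than replicates 2 and 3, which were on different chips (larger difference in r = -0.00809). The replicate 1 array had the fewest detected genes in 2 of 2 groups, but by a small margin. Replicates 1 to 3 had 14732, 14839 and 14987 detected genes in controls and 14691, 15050 and 15170 with aspirin. Lower detection on the replicate 1 arrays may contribute and stays open. No biological explanation was tested, as the labels give the replicates no other property.

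The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. Every other split mixes treated and untreated arrays, so the aspirin difference widens the spread within its groups and partly remains between them. The other splits are therefore not a reference without an effect, and their counts of genes and lists do not measure chance. The real split gave 3059 genes and the highest other 0 by limma (922 at an unadjusted p under 0.05), so 1 of 10 was as large. For lists by camera the real split gave 10 and the highest other 10, and 3 of 10 were as large. Of the 3 other splits that part all 3 replicate pairs, as the real one does, each gave 0 genes (80 to 162 at an unadjusted p under 0.05) and 6 to 10 lists.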
